A study of Mus musculus with 144 samples.

How the data were processed

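RNA of blood leukocytes and spleen cells was measured on Affymetrix whole-genome mouse arrays. Per the labels' protocols, blood came from cardiac puncture, red cells were lysed, RNA was isolated with RNeasy and labelled with the NuGEN Ovation Biotin system. The deposited values are intensity values on a linear scale, which the authors made with MAS5 in GCOS 1.4, per the submitters' processing notes. The values of the burn and trauma-hemorrhage arrays have a mean, with 2% trimmed at each end, of 500, and those of the LPS arrays have smaller trimmed means of 121 to 140.6, whose scaling no label states. The LPS arrays were therefore fitted apart from the others, except where effects were compared. Per the series description the mice were individual animals, and the numbers of the replicates were not taken to pair them. The titles of the trauma-hemorrhage blood arrays contain the word burn while their descriptions give the trauma-hemorrhage model, which was followed, and the descriptions of the burn spleen arrays give that model while their titles say burn spleen, and there the titles were followed.

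Of 45037 probe sets, 64 were controls, 34945 mapped to 1 gene, 932 to several and 9160 to none, and 18193 genes remained with 1 probe set each, the one with the highest mean that was not marked as cross-hybridizing where there was a choice. Of these, 18031 matched a gene of the reference annotation and 162 did not. Genes above the array median on at least 4 arrays were tested: 14656 in blood, 13471 in spleen and 11753 in the LPS set. The fits held 64 blood, 64 spleen and 16 LPS arrays, 80 blood arrays for LPS against injury, and all blood and spleen injury arrays for the comparison of tissues. Values entered as log2(value + 32), so a fold change is a quotient of shifted geometric means. It can lie far from the quotient of the mean signals where arrays spread widely or a signal lies near or below 32. Each injured or treated group was compared with the sham of its own model, tissue and time in limma 3.58.1 (R 4.3.3) with a trended variance, and p was adjusted by Benjamini-Hochberg over the genes of a comparison with a threshold of 0.05. Differences between times, injuries, tissues and stimuli were moderated F tests in limma. No columns were left out.

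The 29 gene lists were written before the data were examined, as were the groups, the tests, the other settings tried and the rule for naming genes. They are B cell, T cell, NK and cytotoxic cell, plasma cell, dendritic cell, monocyte, tissue macrophage, suppressive myeloid, mature neutrophil, neutrophil primary granule, neutrophil secondary and tertiary granule, platelet and megakaryocyte, erythroid, antigen presentation by MHC class II, interferon-stimulated, inflammatory cytokine and chemokine, NF-kB feedback and signalling, Toll-like and innate receptor, immediate-early, glucocorticoid-responsive, heat shock, apoptosis, cell cycle, cytosolic ribosomal protein, oxidative phosphorylation, glycolysis and hypoxia, and pancreas, heart muscle and stroma and vessel as marks of contamination. Of 651 listed genes 584 were on the array. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over 522 tests, of which 234 passed with the preset and 34 with both. Genes named are the 3 largest rises and falls of a comparison whose injured arrays all lie beyond the shams, the 4 smallest p of each difference, up to 4 members of each list described, and a fixed set of 30 genes.

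The number of arrays, 4 per group, limits the precision. On simulated data with 50 changed genes per size, the blood comparison at 2 hr after burn recovered 2%, 28%, 90% and 100% of log2 changes of 0.5, 1, 2 and 3, with 3 false among 113 calls over 14656 genes. The spleen comparison at 2 hr after trauma-hemorrhage recovered 12%, 42%, 90% and 98%, with 2 false of 123 over 13471 genes, and the LPS comparison at 2 hr 20%, 90%, 100% and 100%, with 10 false of 165 over 11753. The test of burn against trauma-hemorrhage in spleen, with differences at 1 day, recovered 0%, 6%, 56% and 78%, with 5 false of 75. Settings chosen before the data were examined were a pseudocount of 1 or 100, no filter, quantile normalization, the mean of all probe sets of a gene, the replicate number or hybridization day as a block, a fit on the groups compared alone, and leaving out each replicate. After the data were seen, 4 more were added: the control level or the Gapdh 3' to 5' ratio, a sign of RNA quality, as a covariate, leaving out dim arrays, and scaling the LPS arrays to the trimmed mean of the others. The control level is the geometric mean of the BioB and BioC spike-in signals, with a median of 6384 in blood, 5711.5 in spleen and 1667.5 in the LPS set.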

Results

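Expression was measured on arrays in mice that had a burn injury, a trauma-hemorrhage injury (tissue trauma with blood loss) or an injection of lipopolysaccharide (LPS), a bacterial cell-wall product, each beside sham animals of its own. The burn and trauma-hemorrhage arms covered blood leukocytes and spleen cells at 2 hr, 1 day, 3 day and 7 day, and the LPS arm covered blood leukocytes at 2 hr and 1 day. Each of the 36 groups had 4 arrays, which the series description ties to individual mice, and this number limits the precision of every value. The median signal of an array was 53.08 to 223.4 in blood, 57.82 to 308.5 in spleen and 23.57 to 29.39 in the LPS set, and arrays of the same group correlated with r between 0.7559 and 0.9896 across probe sets. The level of the spiked hybridization controls, which is high on a dim array after scaling, was over 2 times the median of its set on 15 arrays, and these are named where they belong to a comparison. Signals are mean ± SD of 4 injured and 4 sham arrays, log2 changes are injured minus sham with a standard error (SE), and a gene is said to rise or fall only where its limma adjusted p lies under 0.05. Where a mean signal lies near or below the pseudocount of 32, the size of the fold change rests on that pseudocount. Replicates were left out singly.

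**Figure D1:**
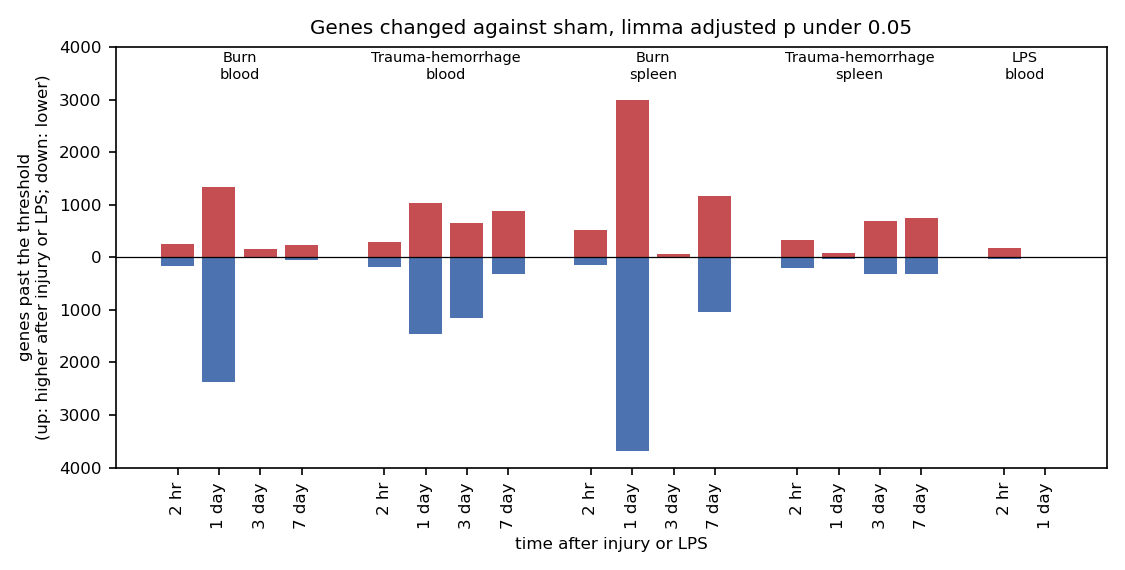
Bars give the number of genes higher (up) and lower (down) than sham at a limma adjusted p under 0.05 in each of the 18 comparisons, with the axis starting at 0. The tallest bars belong to the spleen 1 day after burn, with 2999 genes higher and 3693 lower, and the LPS comparison at 1 day has none.

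At 2 hr after burn, 8 of 22 glucocorticoid-responsive and 3 of 15 neutrophil granule genes rose in blood leukocytes. Mt2, a metal-binding metallothionein, rose 64.8-fold (9530 ± 8450 against 75.3 ± 31.5, limma adjusted p = 1.24e-06), and Fkbp5, a co-chaperone of the glucocorticoid receptor, rose 4.12-fold (2490 ± 395 against 595 ± 201). The clock gene Per1 rose 4.17-fold (log2 change 2.06, SE 0.39) and Errfi1, a feedback inhibitor of the EGF receptor, 4.62-fold. The granule genes Ngp and Ltf (lactoferrin) rose 23.7-fold (4240 ± 1730 against 163 ± 106) and 20.1-fold (1200 ± 664 against 26.8 ± 20.9). Lower were Xkrx (5.69-fold), Xcl1, a chemokine of NK and T cells (5.27-fold), and the chemokine receptor gene Cxcr6 (4.7-fold). Of the 22 glucocorticoid-responsive genes, 8 rose, 0 fell and 14 did not pass (12 and 0 adjusted over the list alone), with camera adjusted p = 5.32e-11 (preset correlation) and adjusted p = 0.00223 (estimated). Among 15 neutrophil secondary and tertiary granule genes, 3 rose, 0 fell and 12 did not pass (8 and 0 adjusted over the list alone), with camera adjusted p = 5.27e-06 (correlation preset) and adjusted p = 0.284 (estimated). With limma, 417 of 14656 genes passed, 251 higher and 166 lower. 21 and 75 passed within the 2 hybridization days, with r = 0.54 between the days over all genes. The Gapdh 3' to 5' ratio lay apart from sham (2.26 to 2.78 against 1.75 to 2.11), and 433 genes passed with it as a covariate. The 417 genes became 198, 219 and 795 without injured replicates 2, 3 and 4, and 252, 701, 150 and 156 without sham replicates 1, 2, 3 and 4. Fkbp5 (1 of 2) had other probe sets, of which this many moved the same way.

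At 1 day after burn, the lymphocyte genes of blood fell widely while glucocorticoid-responsive and granule genes stood higher. Ms4a1, which encodes the B cell protein CD20, was 32-fold lower (355 ± 84.8 against 12100 ± 923, limma adjusted p = 7.02e-16), the lymphocyte GTPase gene Gimap8 24-fold lower (523 ± 148 against 13000 ± 721) and the lymphocyte receptor gene Slamf6 25.5-fold lower. Bank1 and Fcmr, further B cell genes, were 18.8-fold and 19.9-fold lower. Il7r, the interleukin-7 receptor gene of T cells, was 13.9-fold lower, and Bcl11b, a T cell transcription factor, 7.09-fold lower. Among NK cell genes, Klra8 and Klrd1 were 11.8-fold and 5.53-fold lower, and of the MHC class II genes H2-Eb2 was 18.4-fold lower and Ciita, the transactivator of that group, 7.41-fold lower. The interferon-stimulated gene Trim30a was 2.55-fold lower. In the other direction, Mt2 was higher (log2 change 7.01, SE 0.78), Ngp 80.3-fold (16200 ± 596 against 174 ± 50), Camp 51.5-fold and Pdk4, a kinase that restrains pyruvate dehydrogenase, 75.6-fold. The cell-cycle inhibitor gene Cdkn1a was 29.2-fold higher and the decoy interleukin-1 receptor gene Il1r2 was higher (log2 change 5.97, SE 0.63). In the B cell list of 23 genes, 0 rose, 20 fell and 3 did not pass (0 and 21 adjusted over the list alone), with camera adjusted p = 5.02e-21 (preset correlation) and adjusted p = 0.0676 (estimated). For 27 T cell genes, 0 rose, 20 fell and 7 did not pass (0 and 20 adjusted over the list alone), with camera adjusted p = 1.64e-12 (correlation preset) and adjusted p = 0.193 (estimated). Of the 19 NK and cytotoxic cell genes, 1 rose, 11 fell and 7 did not pass (1 and 11 adjusted over the list alone), with camera adjusted p = 0.000438 (preset correlation) and adjusted p = 0.428 (estimated). Among 10 antigen presentation by MHC class II genes, 0 rose, 6 fell and 4 did not pass (0 and 6 adjusted over the list alone), with camera adjusted p = 0.000829 (correlation preset) and adjusted p = 0.439 (estimated). In the glucocorticoid-responsive list of 22 genes, 15 rose, 0 fell and 7 did not pass (18 and 0 adjusted over the list alone), with camera adjusted p = 7.34e-13 (preset correlation) and adjusted p = 0.000617 (estimated). For 15 neutrophil secondary and tertiary granule genes, 9 rose, 0 fell and 6 did not pass (11 and 1 adjusted over the list alone), with camera adjusted p = 2.88e-07 (correlation preset) and adjusted p = 0.233 (estimated). Of the 17 tissue macrophage genes, 8 rose, 1 fell and 8 did not pass (9 and 1 adjusted over the list alone), with camera adjusted p = 0.0116 (preset correlation) and adjusted p = 0.518 (estimated). Among 19 immediate-early genes, 8 rose, 1 fell and 10 did not pass (9 and 1 adjusted over the list alone), with camera adjusted p = 0.000975 (correlation preset) and adjusted p = 0.204 (estimated). With limma, 3712 of 14656 genes passed, 1343 higher and 2369 lower. 2246 and 1659 passed within the 2 hybridization days, with r = 0.74 between the days over all genes.

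By 3 day after burn, nearly every change in blood was a rise, and neutrophil genes led. Stfa3, a stefin protease inhibitor of neutrophils, was 46.1-fold higher (4270 ± 1270 against 61.4 ± 25.4, limma adjusted p = 1.78e-07), and Prok2, a chemokine-like peptide, 38.4-fold higher (4130 ± 865 against 78.3 ± 32.9). Lcn2, an iron-sequestering granule protein, was 10.9-fold higher, the collagenase gene Mmp8 12.1-fold, Cd177 10.8-fold and the annexin gene Anxa1 4.95-fold. Fpr2, a formyl peptide receptor, and Clec4e, a lectin receptor, were 5.03-fold and 6.36-fold higher, and the lipase gene Lipg rose from a sham signal below the pseudocount (1670 ± 1610 against 20.8 ± 24.1). The 3 genes that fell were Ehd2 (3.06-fold), Adgrd1 (2.72-fold) and the RNA helicase gene Ddx50 (1.66-fold). In the mature neutrophil list of 19 genes, 12 rose, 0 fell and 7 did not pass (15 and 1 adjusted over the list alone), with camera adjusted p = 3.65e-30 (preset correlation) and adjusted p = 0.0125 (estimated). For 15 neutrophil secondary and tertiary granule genes, 9 rose, 0 fell and 6 did not pass (13 and 0 adjusted over the list alone), with camera adjusted p = 2.07e-26 (correlation preset) and adjusted p = 0.00416 (estimated). Of the 24 glycolysis and hypoxia genes, 3 rose, 0 fell and 21 did not pass (10 and 0 adjusted over the list alone), with camera adjusted p = 7.96e-12 (preset correlation) and adjusted p = 0.00627 (estimated). After quantile normalization 5 of these rose. With limma, 159 of 14656 genes passed, 156 higher and 3 lower. 30 and 78 passed within the 2 hybridization days, with r = 0.37 between the days over all genes. The 159 genes became 105 and 52 without injured replicates 3 and 4, and 62 without sham replicate 3. The count was 449 fitted on these 8 arrays alone. Lipg (1 of 2) and Ehd2 (2 of 4) had other probe sets, of which this many moved the same way.

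Neutrophil and innate receptor genes were still higher in blood 7 day after burn. Prok2 was 23.9-fold higher (1480 ± 1020 against 23.4 ± 14.9, limma adjusted p = 6.85e-07), Acod1, which makes itaconate, 14.2-fold and the metalloreductase gene Steap4 13.3-fold. Csf3r, the receptor of granulocyte colony-stimulating factor, was 5.33-fold higher, Hdc, which makes histamine, 6.16-fold, and the transcription factor gene Mxd1 3.84-fold. The pattern receptor genes Clec7a, Clec4e and Tlr13 were 3.25-fold, 5-fold and 3.83-fold higher. Sulf1, an extracellular sulfatase, was 9.5-fold lower (32.5 ± 36 against 572 ± 254), and Mgp, a matrix protein, and Gpm6a, a membrane glycoprotein, 7.3-fold and 7.29-fold lower. Among 19 mature neutrophil genes, 14 rose, 0 fell and 5 did not pass (17 and 0 adjusted over the list alone), with camera adjusted p = 1.58e-31 (correlation preset) and adjusted p = 0.0116 (estimated). In the Toll-like and innate receptor list of 23 genes, 8 rose, 0 fell and 15 did not pass (10 and 0 adjusted over the list alone), with camera adjusted p = 5.97e-12 (preset correlation) and adjusted p = 0.0299 (estimated). For 17 stroma and vessel (contamination) genes, 0 rose, 3 fell and 14 did not pass (0 and 6 adjusted over the list alone), with camera adjusted p = 0.000394 (correlation preset) and adjusted p = 0.282 (estimated). With limma, 285 of 14656 genes passed, 238 higher and 47 lower. 119 and 19 passed within the 2 hybridization days, with r = 0.54 between the days over all genes. The 285 genes became 176, 137 and 164 without injured replicates 2, 3 and 4, and 84 and 187 without sham replicates 2 and 4. The count was 1090 fitted on these 8 arrays alone.

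Blood leukocytes 2 hr after trauma-hemorrhage showed a broad rise of interferon-stimulated and NF-kB feedback genes. Cxcl10, a chemokine induced by interferon, was 57.2-fold higher (log2 change 5.84, SE 0.48, limma adjusted p = 2.44e-13), the antiviral gene Ifit3 10.1-fold (5840 ± 1500 against 603 ± 284) and the interferon-inducible GTPase genes Irgm1 and Ifi47 7.42-fold and 4.88-fold. Of the NF-kB genes, Tnfaip3, which encodes the inhibitor A20, was 7.18-fold higher (4690 ± 2450 against 576 ± 227), Nfkbie 5.18-fold and the adhesion gene Icam1 4.87-fold. The lipase gene Lipg was 62.2-fold higher (4260 ± 3020 against 33.7 ± 37.3) and the chemokine receptor-like gene Ccrl2 26.3-fold. The B cell adaptor gene Bank1 was 4.39-fold lower (626 ± 51.1 against 3190 ± 1660), the fucosyltransferase gene Fut4 6.02-fold lower and the spindle gene Tpx2 5.48-fold lower. Of the 33 interferon-stimulated genes, 28 rose, 0 fell and 5 did not pass (31 and 0 adjusted over the list alone), with camera adjusted p = 5.67e-76 (preset correlation) and adjusted p = 1.14e-08 (estimated). Among 19 NF-kB feedback and signalling genes, 9 rose, 0 fell and 10 did not pass (14 and 0 adjusted over the list alone), with camera adjusted p = 6.86e-24 (correlation preset) and adjusted p = 5.28e-06 (estimated). With limma, 477 of 14656 genes passed, 289 higher and 188 lower. 714 and 43 passed within the 2 hybridization days, with r = 0.15 between the days over all genes. Sham replicate 2 was dim, with 2.25 times the median control level. The 477 genes became 296 without injured replicate 1. The count was 134 fitted on these 8 arrays alone. Fut4 (0 of 1) and Tpx2 (1 of 3) had other probe sets, of which this many moved the same way.

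Erythroid and platelet genes passed as higher in blood 1 day after trauma-hemorrhage, interferon-stimulated genes were still up, and B cell genes were lower. Gp1bb, part of the platelet receptor of von Willebrand factor, was 7.25-fold higher (17900 ± 4600 against 2920 ± 1810, limma adjusted p = 0.000246), Selp (P-selectin) 7.94-fold and the integrin gene Itga2b 3.63-fold. Gata1, a transcription factor of red cell precursors, was 4.05-fold higher and the carbonic anhydrase gene Car2 4.79-fold. Irf7, a regulator of interferon genes, was 11-fold higher (4750 ± 2380 against 352 ± 123), Ifit1 13.9-fold and Oas3 7.73-fold. Strong rises were also those of Dst, a cytoskeletal linker (26.4-fold), Gstt1, a glutathione transferase (20.6-fold), and Ngp (19.6-fold, 6690 ± 9250 against 99.2 ± 28.2). Ccr7, the homing receptor of lymphocytes, was 2.75-fold lower (1200 ± 220 against 3340 ± 578), Cd8a 2.59-fold and Cr2, a complement receptor of B cells, 4.02-fold. In the platelet and megakaryocyte list of 18 genes, 16 rose, 0 fell and 2 did not pass (18 and 0 adjusted over the list alone), with camera adjusted p = 1.01e-13 (preset correlation) and adjusted p = 0.202 (estimated). For 24 erythroid genes, 16 rose, 0 fell and 8 did not pass (20 and 0 adjusted over the list alone), with camera adjusted p = 1.46e-11 (correlation preset) and adjusted p = 0.218 (estimated). All 4 injured arrays had control levels above every sham (9184 to 10830 against 5680 to 7012), so injury and array brightness are not separable here. With that level as a covariate, 10 platelet and 6 erythroid genes rose, and their medians went from 1.72 and 1.60 to 1.44 and 0.71. Of the 33 interferon-stimulated genes, 20 rose, 1 fell and 12 did not pass (21 and 1 adjusted over the list alone), with camera adjusted p = 5.32e-13 (preset correlation) and adjusted p = 0.0276 (estimated). Among 23 B cell genes, 1 rose, 17 fell and 5 did not pass (1 and 19 adjusted over the list alone), with camera adjusted p = 5.35e-10 (correlation preset) and adjusted p = 0.283 (estimated). With limma, 2499 of 14656 genes passed, 1033 higher and 1466 lower. 1571 and 133 passed within the 2 hybridization days, with r = 0.47 between the days over all genes. The 2499 genes became 1473 without injured replicate 2. The count was 1483 fitted on these 8 arrays alone. Cd8a (3 of 4) had other probe sets, of which this many moved the same way.

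At 3 day after trauma-hemorrhage, erythroid and oxidative phosphorylation genes were higher in blood, on arrays that were mostly dim. Injured replicates 1, 2 and 4 had 2.11, 2.42 and 2.63 times the median control level, and the comparison without them called 30 genes and 0 of either list. That comparison has 1 injured array, assumed to vary like the other groups. Gstt1 was 52.6-fold higher (18400 ± 3700 against 401 ± 365, limma adjusted p = 3.6e-07), Hjv, an iron regulator, 22.3-fold and Stfa3 14.2-fold. The red cell genes Rhag, Ermap and Tfrc (the transferrin receptor) were 6.62-fold, 6.51-fold and 3.36-fold higher. Cox4i1 and Atp5b, of the respiratory chain and ATP synthase, were 2.01-fold (10500 ± 2170 against 5170 ± 470) and 2.95-fold higher. The growth factor gene Bmp2 was 5.43-fold lower, G530011O06Rik 5.33-fold and the lipoprotein lipase gene Lpl 4.8-fold. In the erythroid list of 24 genes, 15 rose, 0 fell and 9 did not pass (22 and 0 adjusted over the list alone), with camera adjusted p = 1.46e-16 (preset correlation) and adjusted p = 0.112 (estimated). That list had 0 rises with the control level as a covariate. For 34 oxidative phosphorylation genes, 12 rose, 1 fell and 21 did not pass (16 and 1 adjusted over the list alone), with camera adjusted p = 2.65e-09 (correlation preset) and adjusted p = 0.0453 (estimated). With that covariate 10 of these rose. With limma, 1810 of 14656 genes passed, 661 higher and 1149 lower. 595 and 36 passed within the 2 hybridization days, with r = 0.40 between the days over all genes. The median log2 change of all genes was -0.214, and -0.046 after quantile normalization. The Gapdh 3' to 5' ratio lay apart from sham (1.75 to 2.34 against 2.35 to 3.72), and 2528 genes passed with it as a covariate. The 1810 genes became 2729 and 300 without injured replicates 3 and 4, and 741, 1164 and 987 without sham replicates 1, 2 and 4. The count was 1171 after quantile normalization (607 higher and 564 lower), 601 with the control level as a covariate (296 higher and 305 lower), 30 without the dim arrays and 175 fitted on these 8 arrays alone.

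In blood 7 day after trauma-hemorrhage, erythroid genes passed as higher on injured arrays that were all dim, with 2.14 to 3.98 times the median control level. Fech, which inserts iron into heme, was 3.22-fold higher (72600 ± 32100 against 21600 ± 4790, limma adjusted p = 0.000285) and Slc25a37, which brings iron into mitochondria, 3.43-fold. Alas2, the heme synthesis enzyme of red cells, was 3.12-fold higher (95300 ± 34000 against 29900 ± 6990), at up to 52.2% of the highest signal of an array, near the top of the scale, and Bpgm 3.44-fold. Mthfd2, a mitochondrial folate enzyme, was 7.96-fold higher, the prion protein gene Prnp 7.57-fold and Sowaha 9.91-fold. The kinase genes Eef2k and Dguok were 4.5-fold and 4.01-fold lower and Dock9 4.17-fold. Of the 24 erythroid genes, 13 rose, 0 fell and 11 did not pass (23 and 0 adjusted over the list alone), with camera adjusted p = 1.36e-13 (preset correlation) and adjusted p = 0.172 (estimated). The median of that list was 1.66, 1.15 with 7 rises after quantile normalization, and -0.01 with 0 with the control level as a covariate. That covariate nearly stands for the injury here, since the shams lay at 0.9129 to 1.305 times the median, so injury and dimness cannot be separated. Among 25 cytosolic ribosomal protein genes, 7 rose, 1 fell and 17 did not pass (10 and 1 adjusted over the list alone), with camera adjusted p = 0.00405 (correlation preset) and adjusted p = 0.591 (estimated). Its median of 0.32 turned to -0.25 after quantile normalization, where 0 rose. With limma, 1185 of 14656 genes passed, 876 higher and 309 lower. 1 and 240 passed within the 2 hybridization days, with r = 0.43 between the days over all genes. The median log2 change of all genes was 0.064, and -0.044 after quantile normalization. The 1185 genes became 2021 and 272 without injured replicates 2 and 3, and 664, 574 and 732 without sham replicates 1, 2 and 3. The count was 654 with a pseudocount of 1, 737 after quantile normalization (410 higher and 327 lower), 0 with the control level as a covariate, 343 with the Gapdh ratio as a covariate and 226 fitted on these 8 arrays alone. Eef2k (1 of 2) and Dock9 (2 of 4) had other probe sets, of which this many moved the same way. No fit without dim arrays was possible.

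**Figure D2:**
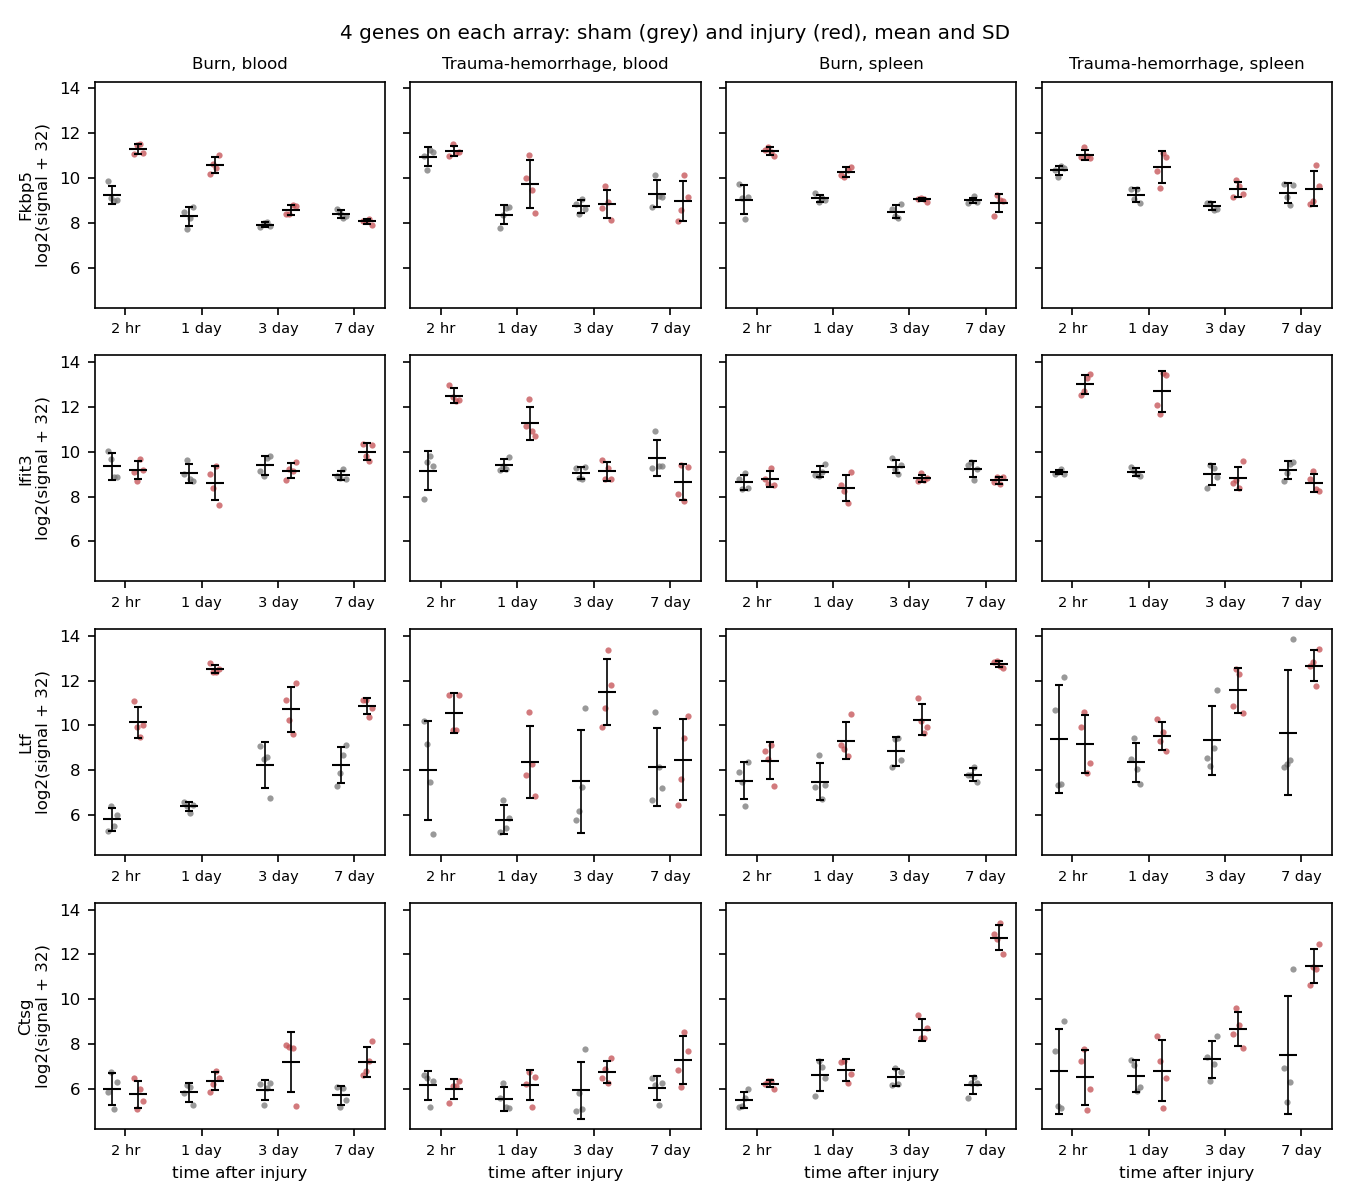
Points are the log2(signal + 32) values of single arrays for Fkbp5, Ifit3, Ltf and Ctsg in injured and sham groups at each time, with the mean and SD of 4 arrays. Ifit3 stands apart from sham at 2 hr after trauma-hemorrhage in blood and spleen, and Ctsg at 7 day after burn in the spleen.

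In the spleen 2 hr after burn, glucocorticoid-responsive genes were higher and heat shock genes lower. Fkbp5 was 4.44-fold higher (2310 ± 287 against 529 ± 225, limma adjusted p = 6.49e-08), Sesn1, a stress-responsive inhibitor of mTOR signalling, 3.78-fold, Per1 4.13-fold and Klf9 4.19-fold. Hsph1, a large heat shock chaperone, was 3.69-fold lower (7300 ± 753 against 27300 ± 5290), Dnaja1 2.18-fold, Chordc1 1.99-fold and Hspa1a, an inducible HSP70 gene, 6.94-fold. Cirbp, an RNA-binding protein induced by cold, was 6.36-fold higher (2210 ± 257 against 326 ± 77.8), the neutrophil chemokine gene Cxcl2 10.4-fold (3110 ± 171 against 273 ± 58.7) and the LPS co-receptor gene Cd14 6.29-fold. The dynein light chain gene Dynll1 was 3.66-fold lower and Zmat4 4.06-fold. In the glucocorticoid-responsive list of 22 genes, 8 rose, 0 fell and 14 did not pass (9 and 0 adjusted over the list alone), with camera adjusted p = 4e-09 (preset correlation) and adjusted p = 0.000617 (estimated). For 13 heat shock genes, 1 rose, 7 fell and 5 did not pass (1 and 8 adjusted over the list alone), with camera adjusted p = 4.71e-09 (correlation preset) and adjusted p = 0.0373 (estimated). With limma, 661 of 13471 genes passed, 512 higher and 149 lower. 243 and 59 passed within the 2 hybridization days, with r = 0.37 between the days over all genes. Sham replicates 1 and 3 were dim, with 2.00 and 6.78 times the median control level. The 661 genes became 414, 412 and 379 without injured replicates 1, 2 and 4, and 992 without sham replicate 4. The count was 973 after quantile normalization (648 higher and 325 lower), 543 with the control level as a covariate (319 higher and 224 lower), 411 without the dim arrays and 55 fitted on these 8 arrays alone. Fkbp5 (1 of 2) and Klf9 (3 of 6) had other probe sets, of which this many moved the same way.

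The spleen 1 day after burn had the most changed genes of the 18 comparisons, and lymphocyte, NK cell and monocyte genes fell together. Ms4a1 was 8.69-fold lower (1330 ± 253 against 11700 ± 447, limma adjusted p = 4.03e-26), the B cell transcription factor gene Spib 7.45-fold, Cr2 7.05-fold and the follicle-homing receptor gene Cxcr5 9.73-fold. Of the T cell genes, Ms4a4b was 9.45-fold lower, Cd8a 9.35-fold (516 ± 104 against 5020 ± 98.2) and Bcl11b 4.69-fold. The granzyme gene Gzma was 5.69-fold lower and Nkg7 6.89-fold. Ms4a4c was 24.3-fold lower (94.5 ± 51.1 against 2870 ± 403), the single-strand DNA binding protein gene Nabp1 18-fold, the non-coding RNA gene Dleu2 15.9-fold and the monocyte chemokine receptor gene Ccr2 6.44-fold. Among interferon-stimulated genes, Usp18 was 5.95-fold lower and Gbp2 4.93-fold. Mt2 was 13-fold higher (5140 ± 524 against 368 ± 54.5), Cdkn1a 7.37-fold, Errfi1 3.11-fold and Gm26611 14.6-fold. 4933438K21Rik was 14.8-fold higher, lowest on injured replicate 4 (not dim). Of the 23 B cell genes, 0 rose, 19 fell and 4 did not pass (0 and 20 adjusted over the list alone), with camera adjusted p = 3.59e-12 (preset correlation) and adjusted p = 0.126 (estimated). Among 27 T cell genes, 1 rose, 22 fell and 4 did not pass (1 and 22 adjusted over the list alone), with camera adjusted p = 4.24e-10 (correlation preset) and adjusted p = 0.112 (estimated). In the NK and cytotoxic cell list of 19 genes, 0 rose, 16 fell and 3 did not pass (0 and 16 adjusted over the list alone), with camera adjusted p = 5.21e-07 (preset correlation) and adjusted p = 0.0338 (estimated). For 18 monocyte genes, 2 rose, 12 fell and 4 did not pass (2 and 12 adjusted over the list alone), with camera adjusted p = 0.000724 (correlation preset) and adjusted p = 0.27 (estimated). Of the 34 interferon-stimulated genes, 0 rose, 20 fell and 14 did not pass (0 and 20 adjusted over the list alone), with camera adjusted p = 0.000203 (preset correlation) and adjusted p = 0.414 (estimated). Among 22 glucocorticoid-responsive genes, 14 rose, 1 fell and 7 did not pass (15 and 1 adjusted over the list alone), with camera adjusted p = 3.14e-05 (correlation preset) and adjusted p = 0.0162 (estimated). In the heart muscle (contamination) list of 9 genes, 5 rose, 1 fell and 3 did not pass (6 and 1 adjusted over the list alone), with camera adjusted p = 0.0608 (preset correlation) and adjusted p = 0.467 (estimated). Of 16 stroma and vessel genes 4 rose and 1 fell (median 0.86). With the control level as a covariate 0 genes of either list rose and 12 interferon-stimulated genes fell, and without the dim arrays 0 rose, 8 fell and 9 glucocorticoid-responsive genes rose. With limma, 6692 of 13471 genes passed, 2999 higher and 3693 lower. 5551 and 2296 passed within the 2 hybridization days, with r = 0.81 between the days over all genes. Injured replicates 1, 2 and 3 were dim, with 3.09, 3.42 and 4.30 times the median control level, and the comparison without them has 1 injured array, assumed to vary like the other groups. The 6692 genes became 3951 with the control level as a covariate (1255 higher and 2696 lower) and 2848 without the dim arrays. Dleu2 (1 of 2) had other probe sets, of which this many moved the same way.

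At 3 day after burn, few spleen genes changed, and neutrophil genes led the rises. Cxcl2 was 10.9-fold higher (2840 ± 518 against 244 ± 112, limma adjusted p = 0.0244), Prok2 9.52-fold (799 ± 465 against 48.7 ± 24.5), Mmp8 8.89-fold and Lcn2 7.48-fold. The haptoglobin gene Hp was 5.47-fold higher, the stefin gene Stfa2l1 6.97-fold, Clec4e 6.62-fold and Alox5ap, which serves leukotriene synthesis, 2.78-fold. Mmp12, a macrophage elastase, was 3.41-fold lower, the sodium channel gene Scn3a 3.44-fold and Maged1 3.46-fold (10.8 ± 3.62 against 120 ± 40.1). For 19 mature neutrophil genes, 5 rose, 0 fell and 14 did not pass (16 and 0 adjusted over the list alone), with camera adjusted p = 1.29e-21 (correlation preset) and adjusted p = 0.0253 (estimated). After quantile normalization 8 of these rose. Of the 14 dendritic cell genes, 0 rose, 2 fell and 12 did not pass (0 and 5 adjusted over the list alone), with camera adjusted p = 6.57e-05 (preset correlation) and adjusted p = 0.0253 (estimated). With limma, 74 of 13471 genes passed, 65 higher and 9 lower. 109 and 0 passed within the 2 hybridization days, with r = 0.44 between the days over all genes. Sham replicate 2 was dim, with 2.20 times the median control level. The Gapdh 3' to 5' ratio lay apart from sham (1.89 to 2.13 against 2.27 to 3.21), and 51 genes passed with it as a covariate. The 74 genes became 16, 32, 48 and 47 without injured replicates 1, 2, 3 and 4, and 14 and 25 without sham replicates 1 and 4. The count was 46 with the mean of all probe sets of a gene, 95 with the control level as a covariate (73 higher and 22 lower), 168 without the dim arrays and 130 fitted on these 8 arrays alone. Prok2 (1 of 2) had other probe sets, of which this many moved the same way.

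By 7 day after burn the spleen carried much more RNA of neutrophil primary granule, red cell precursor and cell cycle genes. The granule protease genes Ctsg, Elane and Prtn3 were 95.8-fold (7260 ± 2730 against 42 ± 18.9, limma adjusted p = 1.23e-09), 39.3-fold and 45.5-fold higher, and the myeloperoxidase gene Mpo 58.6-fold (8990 ± 1790 against 122 ± 32.1). Ermap, a red cell membrane gene, was 47.4-fold higher, Tal1, a blood cell transcription factor, 34.3-fold and Cldn13 31.9-fold. Cdk1, the kinase that drives mitosis, was 11.1-fold higher (2910 ± 1140 against 221 ± 65), Rrm2, a subunit of ribonucleotide reductase, 13.6-fold and Ube2c 13.2-fold. T cell genes were lower, with Cd6 3.01-fold, Ccr7 2.65-fold and the adaptor gene Lat 2.62-fold below sham. Spib and Cd79b, of B cells, were 2.05-fold and 1.72-fold lower, Mmp12 3.35-fold and A630023P12Rik 2.94-fold. Among 8 neutrophil primary granule genes, 6 rose, 0 fell and 2 did not pass (6 and 0 adjusted over the list alone), with camera adjusted p = 7.91e-13 (correlation preset) and adjusted p = 0.00831 (estimated). In the erythroid list of 23 genes, 23 rose, 0 fell and 0 did not pass (23 and 0 adjusted over the list alone), with camera adjusted p = 1.79e-32 (preset correlation) and adjusted p = 0.0253 (estimated). For 35 cell cycle genes, 33 rose, 0 fell and 2 did not pass (35 and 0 adjusted over the list alone), with camera adjusted p = 1.2e-43 (correlation preset) and adjusted p = 0.0162 (estimated). Of the 27 T cell genes, 0 rose, 23 fell and 4 did not pass (0 and 26 adjusted over the list alone), with camera adjusted p = 5.13e-20 (preset correlation) and adjusted p = 0.0122 (estimated). With limma, 2209 of 13471 genes passed, 1159 higher and 1050 lower. 1657 and 187 passed within the 2 hybridization days, with r = 0.81 between the days over all genes. The 2209 genes became 3654 fitted on these 8 arrays alone.

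In the spleen 2 hr after trauma-hemorrhage, 33 of 34 interferon-stimulated genes rose, with inflammatory and NF-kB genes. Cxcl10 was 27-fold higher (4020 ± 1030 against 114 ± 10.8, limma adjusted p = 2.13e-15), the antiviral genes Mx2, Ifit3 and Ifit2 15.8-fold, 15.1-fold (8440 ± 2540 against 511 ± 37.1) and 10.6-fold, and Acod1 22.7-fold (2920 ± 606 against 106 ± 57.9). The chemokine genes Ccl4 and Ccl3 were 11.9-fold and 5-fold higher, the interleukin-1 receptor antagonist gene Il1rn 7.92-fold and the anti-inflammatory cytokine gene Il10 6.14-fold. Socs3, a suppressor of cytokine signalling, was 8.04-fold higher, Bcl3 3.8-fold and Tnfaip3 2.6-fold. The potassium channel gene Kcnj16 was 6.92-fold lower (115 ± 62 against 945 ± 267), Hpgd, which breaks down prostaglandins, 6.13-fold and Tmem86a 3.63-fold. Among 34 interferon-stimulated genes, 33 rose, 0 fell and 1 did not pass (34 and 0 adjusted over the list alone), with camera adjusted p = 4.47e-129 (correlation preset) and adjusted p = 1.1e-09 (estimated). In the inflammatory cytokine and chemokine list of 22 genes, 10 rose, 0 fell and 12 did not pass (16 and 0 adjusted over the list alone), with camera adjusted p = 1.47e-22 (preset correlation) and adjusted p = 0.000191 (estimated). For 19 NF-kB feedback and signalling genes, 8 rose, 0 fell and 11 did not pass (11 and 0 adjusted over the list alone), with camera adjusted p = 2.14e-16 (correlation preset) and adjusted p = 0.00416 (estimated). Of the 17 suppressive myeloid genes, 5 rose, 0 fell and 12 did not pass (6 and 0 adjusted over the list alone), with camera adjusted p = 2.74e-05 (preset correlation) and adjusted p = 0.0433 (estimated). Among 16 pancreas (contamination) genes, 0 rose, 0 fell and 16 did not pass (0 and 10 adjusted over the list alone), with camera adjusted p = 2.88e-07 (correlation preset) and adjusted p = 0.283 (estimated). With limma, 535 of 13471 genes passed, 334 higher and 201 lower. 205 and 152 passed within the 2 hybridization days, with r = 0.55 between the days over all genes. The 535 genes became 348 without injured replicate 4. The count was 1083 fitted on these 8 arrays alone.

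The interferon-stimulated genes were still higher in the spleen 1 day after trauma-hemorrhage, while few other genes passed. Ifit3 was 12.1-fold higher (7600 ± 4400 against 518 ± 67.7, limma adjusted p = 4.77e-14), Ifit1 9.38-fold (6620 ± 3120 against 657 ± 270), Irf7 7.93-fold and Ifit2 5.64-fold. Fkbp5 was higher (log2 change 1.25, SE 0.27). Ctnnd2, a delta-catenin, was 3.64-fold lower (90.4 ± 61 against 358 ± 74.7), the calmodulin regulator gene Pcp4 3.15-fold and the dendritic cell lectin gene Cd209a 3.14-fold. In the interferon-stimulated list of 34 genes, 28 rose, 0 fell and 6 did not pass (33 and 0 adjusted over the list alone), with camera adjusted p = 3.43e-117 (preset correlation) and adjusted p = 2.59e-09 (estimated). With limma, 115 of 13471 genes passed, 89 higher and 26 lower. 12 and 157 passed within the 2 hybridization days, with r = 0.16 between the days over all genes. The 115 genes became 187, 246, 68 and 62 without injured replicates 1, 2, 3 and 4. The count was 47 fitted on these 8 arrays alone. Fkbp5 (1 of 2) and Ctnnd2 (0 of 1) had other probe sets, of which this many moved the same way.

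Cell cycle and erythroid genes rose in the spleen 3 day after trauma-hemorrhage, and T cell genes fell. Ccne1 (cyclin E1) was 3.97-fold higher (2080 ± 640 against 525 ± 245, limma adjusted p = 3.97e-05), Rrm2 5.94-fold and the replication helicase genes Mcm6 and Mcm2 2.71-fold and 2.9-fold. Gata1 was 3.98-fold higher, Rhag 6.82-fold, Car1 5.52-fold and Pklr, the pyruvate kinase gene of red cells and liver, 9.17-fold. The sialomucin gene Podxl was 17.7-fold higher (2240 ± 282 against 103 ± 50.6) and Mt2 13.8-fold (7720 ± 3710 against 656 ± 563). Cd8a was 2-fold lower (2670 ± 410 against 5340 ± 255), Cd6 2.22-fold and Cd5 1.74-fold. Polr2e, an RNA polymerase subunit, was 3.06-fold lower, Axin2, a brake on Wnt signalling, 2.66-fold and Enkur 2.62-fold. For 35 cell cycle genes, 33 rose, 0 fell and 2 did not pass (34 and 0 adjusted over the list alone), with camera adjusted p = 7.61e-38 (correlation preset) and adjusted p = 0.027 (estimated). Of the 23 erythroid genes, 12 rose, 0 fell and 11 did not pass (16 and 0 adjusted over the list alone), with camera adjusted p = 1.02e-12 (preset correlation) and adjusted p = 0.233 (estimated). Among 27 T cell genes, 0 rose, 18 fell and 9 did not pass (0 and 21 adjusted over the list alone), with camera adjusted p = 8.18e-16 (correlation preset) and adjusted p = 0.0264 (estimated). In the plasma cell list of 14 genes, 2 rose, 0 fell and 12 did not pass (6 and 1 adjusted over the list alone), with camera adjusted p = 0.00403 (preset correlation) and adjusted p = 0.298 (estimated). With limma, 1016 of 13471 genes passed, 692 higher and 324 lower. 511 and 3 passed within the 2 hybridization days, with r = 0.57 between the days over all genes. The 1016 genes became 448 without injured replicate 4, and 518 and 528 without sham replicates 2 and 3. The count was 1096 after quantile normalization (636 higher and 460 lower) and 1547 with the control level as a covariate (843 higher and 704 lower). Mcm6 (1 of 2), Polr2e (1 of 2) and Axin2 (0 of 1) had other probe sets, of which this many moved the same way.

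At 7 day after trauma-hemorrhage, erythroid, cell cycle and primary granule genes were higher in the spleen, with a wide spread among the shams. Klf1, the main transcription factor of red cell genes, was 24.3-fold higher (3340 ± 670 against 416 ± 761, limma adjusted p = 0.000182), Ermap 18.8-fold (10400 ± 4990 against 1140 ± 1770), Gata1 6.98-fold and Tal1 13.2-fold. Cdc6, which loads replication origins, was 6.28-fold higher, Ccne1 4.7-fold and Rrm2 6.5-fold. Ctsg and Mpo were 15.6-fold (3130 ± 1740 against 677 ± 1250) and 12.2-fold higher, and 5430401H09Rik 19-fold. The B cell genes Cd72 and Ms4a1 were 2.02-fold and 1.56-fold lower, the ectodysplasin adaptor gene Edaradd 2.9-fold and Crybg2 2.8-fold. For 23 erythroid genes, 23 rose, 0 fell and 0 did not pass (23 and 0 adjusted over the list alone), with camera adjusted p = 3.27e-31 (correlation preset) and adjusted p = 0.027 (estimated). Of the 35 cell cycle genes, 33 rose, 0 fell and 2 did not pass (34 and 0 adjusted over the list alone), with camera adjusted p = 7.73e-45 (preset correlation) and adjusted p = 0.0152 (estimated). Among 8 neutrophil primary granule genes, 6 rose, 0 fell and 2 did not pass (6 and 0 adjusted over the list alone), with camera adjusted p = 1.79e-07 (correlation preset) and adjusted p = 0.0596 (estimated). With limma, 1052 of 13471 genes passed, 743 higher and 309 lower. 1762 and 0 passed within the 2 hybridization days, with r = 0.39 between the days over all genes. Sham replicate 4 lay at 0.65 of the way from burn sham to burn injury at this time, against 0.06 to 0.17 for the other shams of 7 day, and shams of 2 hr and 3 day reached 0.53 and 0.45. Without sham replicate 4 the log2 changes moved (Klf1 4.61 to 5.79, Ctsg 3.97 to 5.24, Mpo 3.61 to 4.77, Ermap 4.23 to 5.20). Sham replicate 2 was dim, with 3.6 times the median control level. The 1052 genes became 1425 after quantile normalization (811 higher and 614 lower), 1725 with the control level as a covariate (890 higher and 835 lower) and 342 fitted on these 8 arrays alone.

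**Figure D3:**
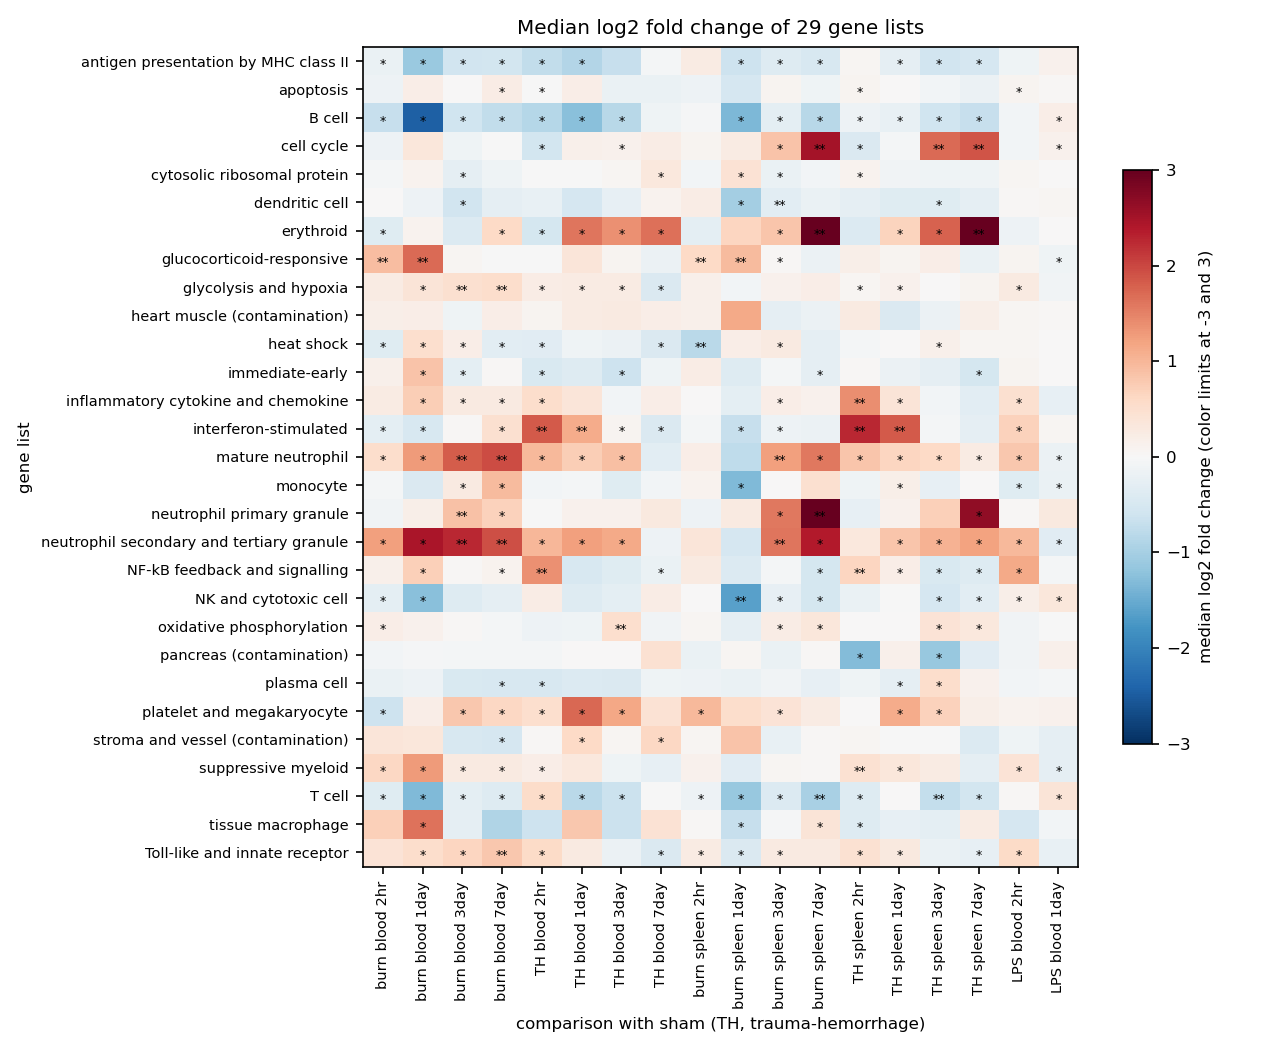
Colours give the median log2 change (injured minus sham) of the 29 gene lists in the 18 comparisons, * marks a list that passes camera with the preset correlation and ** a list that passes with an estimated correlation too. The interferon-stimulated list carries ** at 2 hr after trauma-hemorrhage in blood and spleen, and the erythroid list at 7 day in the spleen after both injuries.

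At 2 hr after LPS, 8 of 19 NF-kB feedback, 4 of 15 granule and 4 of 14 apoptosis genes rose in blood. The granule genes Camp (cathelicidin) and Ltf were 11.5-fold (1250 ± 126 against 279 ± 518, limma adjusted p = 0.0107) and 8.43-fold higher, and Lipg 7.66-fold (495 ± 68 against 60.6 ± 93.4) and Ccrl2 9.22-fold. Relb, an NF-kB subunit, was 3.12-fold higher (365 ± 37 against 108 ± 77.5), its inhibitor gene Nfkbie 3.64-fold and Irak3, a brake on Toll-like receptor signals, 3.05-fold. The death receptor gene Fas was 3.6-fold higher and Apaf1, of the apoptosome, 2.03-fold. Cxcl10 was 5.86-fold higher (905 ± 221 against 363 ± 637) and Gbp2 3.59-fold. The low-density lipoprotein receptor family gene Ldlrad3 was 4.98-fold lower (78.7 ± 29.7 against 631 ± 367), Hpgd 4.45-fold and the transporter gene Abca9 3.21-fold. In the NF-kB feedback and signalling list of 19 genes, 8 rose, 0 fell and 11 did not pass (19 and 0 adjusted over the list alone), with camera adjusted p = 3.79e-20 (preset correlation) and adjusted p = 0.1 (estimated). For 15 neutrophil secondary and tertiary granule genes, 4 rose, 0 fell and 11 did not pass (5 and 0 adjusted over the list alone), with camera adjusted p = 9.88e-09 (correlation preset) and adjusted p = 0.284 (estimated). Of the 14 apoptosis genes, 4 rose, 0 fell and 10 did not pass (5 and 0 adjusted over the list alone), with camera adjusted p = 0.000102 (preset correlation) and adjusted p = 0.0596 (estimated). With limma, 216 of 11753 genes passed, 175 higher and 41 lower, and sham replicate 4 lay at 0.78 of the way from the other shams to the treated arrays over the 422 genes called without it. Leaving it out moved log2 changes (Camp 3.53 to 4.63, Ltf 3.08 to 4.06, Ccrl2 3.21 to 4.13, Cxcl10 2.55 to 3.59). No hybridization day is known. The Gapdh 3' to 5' ratio lay apart from sham (1.4 to 1.54 against 1.62 to 2.01), and 227 genes passed with it as a covariate. The 216 genes became 89, 77 and 118 without treated replicates 1, 3 and 4, and 94, 141 and 422 without sham replicates 1, 2 and 4. The count was 135 with the control level as a covariate, 194 with the arrays scaled to the trimmed mean of the injury arrays (66 of them lower) and 7 fitted on these 8 arrays alone.

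At 1 day after LPS, 0 of 11753 genes passed with limma, and 1287 had an unadjusted p under 0.05. Among 27 T cell genes, 0 rose, 0 fell and 27 did not pass (10 and 0 adjusted over the list alone), with camera adjusted p = 2.84e-09 (correlation preset) and adjusted p = 0.309 (estimated). The 0 genes became 2 without treated replicate 3, and 1 without sham replicate 2.

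**Figure D4:**
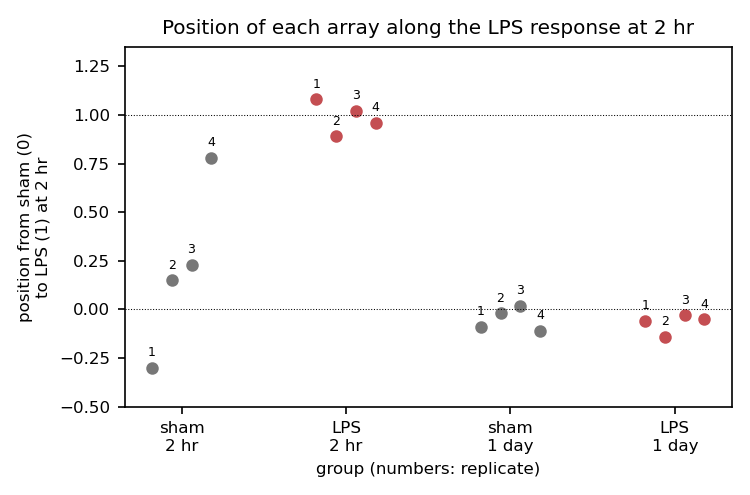
Points place each LPS and LPS sham array on the axis from the 2 hr shams without replicate 4 (0) to the treated arrays (1) at 2 hr, over 422 genes. Sham replicate 4 lies at 0.78 and all arrays of 1 day lie between -0.14 and 0.02.

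The effect of an injury was next compared between times, with a limma F test of 1 day, 3 day and 7 day each against 2 hr. In blood after burn, 2045 of 14656 genes differed, led by Gimap8, whose effect at 1 day lay by -3.99 from that at 2 hr (limma adjusted p = 4.06e-17), the kinase gene Cdk19 (-3.05), the gene-silencing factor gene Tasor (-3.41) and Samd9l, an antiviral gene (-2.32). In the spleen after burn 6021 of 13471 differed, and Ms4a4c (-3.13, limma adjusted p = 2.04e-19), Nabp1 (-3.68), Ms4a1 (-2.48) and Gimap8 (-3.06) also moved most at 1 day. After trauma-hemorrhage the leading genes were those that rose at 2 hr. In blood 1348 differed, with Pmvk, an enzyme of sterol synthesis, at -4.35 by 1 day (limma adjusted p = 2.38e-11), Cgas, a sensor of cytosolic DNA, at -4.78 by 3 day, and Parp9 (-3.16) and Cxcl10 (-5.99) by 7 day. In the spleen 1118 differed, led by the interferon-stimulated genes Ifit3 (-4.49 by 7 day, limma adjusted p = 4.11e-15), Mx1 (-4.68 by 3 day), Ifit2 (-3.54 by 7 day) and Ifi213 (-2.30 by 7 day). For LPS, 27 of 11753 genes differed between 1 day and 2 hr, among them F3, the tissue factor gene (-1.89, limma adjusted p = 0.0343), Cldn1 (-1.69), Mthfs (-1.59) and Gpr25 (-0.91). The 2045 genes became 1163, 916, 1202 and 1257 without replicates 1, 2, 3 and 4, the 6021 became 3784 without replicate 3, the 1348 became 544 without replicate 2, the 1118 became 546, 651 and 716 without replicates 1, 3 and 4 and the 27 became 0, 0, 0 and 154 without replicates 1, 2, 3 and 4. Other settings gave 3663 fitted on the groups compared alone for burn in blood, 3808 with the control level as a covariate and 2980 without the dim arrays for burn in spleen, 834 with the control level as a covariate and 222 fitted on the groups compared alone for trauma-hemorrhage in blood and 1 with a pseudocount of 1, 43 with a pseudocount of 100, 13 with no filter, 9 after quantile normalization, 15 with the control level as a covariate, 85 with the Gapdh ratio as a covariate and 2 with the arrays scaled to the trimmed mean of the injury arrays for LPS.

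Burn and trauma-hemorrhage were compared directly, each against its own sham. In blood the effect of 2839 of 14656 genes differed over the 4 times, and tests of each time alone gave 161 at 2 hr, 2318 at 1 day, 51 at 3 day and 345 at 7 day. The interferon-stimulated genes Ifit1bl1 and Ifi47 lay lower after burn by -4.05 and -2.85 at 2 hr, where they had changed by 2.48 and 2.29 after trauma-hemorrhage (limma adjusted p = 5.88e-14 for Ifit1bl1 and 1.05e-10 for Ifi47). Samd9l and Gimap8 lay lower after burn by -3.66 and -3.79 at 1 day. In the spleen 2628 of 13471 differed, and 294, 4176, 3 and 0 genes at the 4 times alone. On simulated data with independent noise for each gene, this test recovered 6% and 56% of log2 differences of 1 and 2 placed at 1 day. At 1 day the difference was -5.52 for Ms4a4c (limma adjusted p = 1.62e-23), -5.06 for Usp18, a regulator of interferon signalling that changed by -2.57 after burn and 2.49 after trauma-hemorrhage, -3.83 for Samd9l and -3.29 for Ms4a4b. The correlation of the effects across genes, which are not independent, was 0.17, 0.32, 0.23 and -0.00 in blood and 0.17, -0.05, 0.56 and 0.78 in spleen at the 4 times. In the spleen at 7 day, 631 genes rose after both injuries, against 63.9 for independent lists, 207 fell in both, against 24.1, and 0 moved in opposite directions. The 2839 genes became 1247, 1594 and 1735 without replicates 1, 2 and 4, the 2628 became 1271 and 1399 without replicates 1 and 2, and 1655 without the dim arrays. Burn and trauma-hemorrhage arrays were hybridized on different days, which cancels only as far as each sham shares the day of its injury.

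Blood and spleen were compared in the same way over 15623 genes. After burn the effect of 1701 genes differed (24, 1896, 1 and 472 at the 4 times alone), and at 1 day blood lay above spleen by 3.17 for Pmvk (limma adjusted p = 3.36e-13), 2.63 for Rabgef1, a regulator of endosome traffic, 3.23 for Themis2 and 4.12 for Selenon, a selenoprotein. After trauma-hemorrhage 2023 differed (16, 913, 906 and 364 at the 4 times alone). Blood lay above spleen by 4.87 for Dst at 1 day (limma adjusted p = 9.31e-09) and 4.64 for Hjv at 3 day, and below it by -1.99 for Pnpt1, an RNA-degrading enzyme of mitochondria, at 1 day and -2.02 for Pcna, the replication clamp, at 3 day. Falls in both tissues 1 day after burn numbered 1866 genes, against 675 for independent lists, rises 496, against 265, and 139 genes moved in opposite directions. At 2 hr after trauma-hemorrhage 141 genes rose in both tissues, against 7.19, and 0 moved in opposite directions. The 1701 genes became 702, 544 and 605 without replicates 1, 2 and 3, and 975 without the dim arrays. The 2023 became 1108 and 1044 without replicates 1 and 2, with 1331 after quantile normalization, 1330 with the control level as a covariate and 960 fitted on the groups compared alone.

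The LPS effect in blood was set against each injury at 2 hr and 1 day over 15138 genes. Against burn, 2527 genes differed (75 at 2 hr and 2817 at 1 day, each alone), and at 1 day LPS lay above burn by 4.80 for Gimap8 (limma adjusted p = 2.91e-20), 4.03 for Tasor, 3.37 for Cdk19 and 3.57 for Samd9l. Against trauma-hemorrhage 657 differed (17 and 1173). At 2 hr LPS lay below trauma-hemorrhage by -3.64 for Pmvk (limma adjusted p = 4.32e-09), -1.99 for Ifi47 and -2.21 for Irgm1, and at 1 day by -2.00 for Lgals9, the galectin-9 gene. At 2 hr the genes raised by LPS and by trauma-hemorrhage shared 77 members, against 4.14 for independent lists, and those lowered shared 12, against 0.661, with 0 in opposite directions. LPS and burn shared 15 raised genes, against 2.85. The 2527 genes became 1570 and 1574 without replicates 2 and 3, and 4312 fitted on the groups compared alone, and the 657 became 267, 74 and 130 without replicates 1, 2 and 3, and 1166 with the Gapdh ratio as a covariate and 1482 without the dim arrays.

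**Figure D5:**
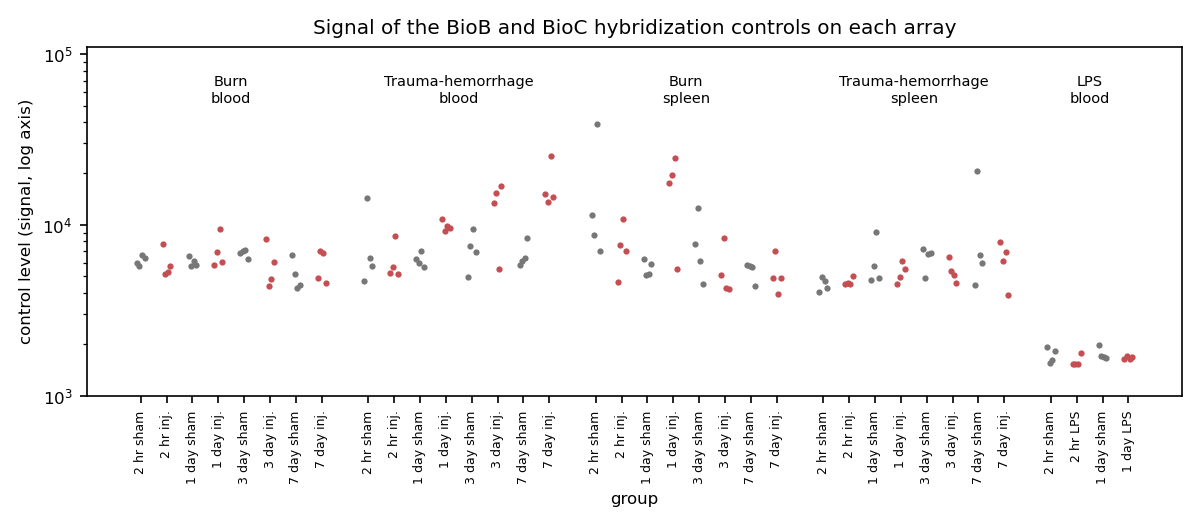
Points give the hybridization control level of each array on a log axis, by group. The 15 dim arrays, over 2 times the median of their set, include all 4 injured blood arrays 7 day after trauma-hemorrhage.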

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

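The tests of other splits of the arrays were written before the results were seen, and all other tests here after, except where a sentence says otherwise. In 240 groups of 4 values, 20 held an array far from the other 3 by the gap over the range, given here, and chance gives about 1 in 20 groups, or 12. For the hybridization control level these were burn sham spleen at 7 day (replicate 4 lowest, 0.914), LPS treated at 2 hr (replicate 4 highest, 0.975), trauma-hemorrhage blood at 2 hr (replicate 3 highest, 0.836) and 7 day (replicate 3 highest, 0.831), trauma-hemorrhage spleen at 2 hr (replicate 4 highest, 0.84) and its sham at 3 day (replicate 2 lowest, 0.858). Among genes in burn blood, sham replicate 3 at 1 day was highest for Mt2 (0.866) and lowest for Slamf6 (0.868), and injured replicate 4 at 3 day lowest for Ddx50 (0.862). In trauma-hemorrhage blood, injured replicate 3 at 2 hr was lowest for Cxcl10 (0.844), injured replicate 2 at 2 hr highest for Fut4 (0.897) and sham replicate 2 at 3 day lowest for Hjv (0.88). In injured burn spleens, replicate 4 was lowest at 1 day for 4933438K21Rik (0.885) and at 7 day for Ermap (0.871). At 3 day replicate 3 was highest for Mmp12 (0.971). In trauma-hemorrhage spleen, sham replicate 1 at 2 hr was highest for Mx2 (0.848), sham replicate 3 at 2 hr lowest for Tmem86a (0.872) and injured replicate 4 at 3 day highest for Mt2 (0.942). For Camp at 2 hr, LPS treated replicate 4 was lowest (0.934) and LPS sham replicate 4 highest (0.925).

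Gene counts of the 11 limma F tests were compared with other splits of the arrays. Of 100 splits, the true one included, 1 gave as many genes for times in burn blood (2045, highest other 433), burn spleen (6021, 4038) and trauma-hemorrhage spleen (1118, 912), for burn against trauma-hemorrhage in blood (2839, 1348), blood against spleen after trauma-hemorrhage (2023, 1131), and LPS against burn (2527, 1571) and trauma-hemorrhage (657, 470). For LPS times 2 did (27, 105), for burn against trauma-hemorrhage in spleen 2 (2628, 2716), and for times in trauma-hemorrhage blood (1348, 2155) and blood against spleen after burn (1701, 3083) 3 did. Against sham, of 35 splits, chance cannot be excluded for burn blood at 2 hr (2 as large, 417 genes, highest other 530), trauma-hemorrhage blood at 3 day (2, 1810, 2206), burn spleen at 2 hr (2, 661, 984), trauma-hemorrhage spleen at 1 day (5, 115, 512) and LPS at 1 day (35, 0, 2). The 2206 and 984 are splits by control level, which thus called more genes than injury. In the other 13 only the true split was as large, the least share possible. In trauma-hemorrhage blood at 7 day that is also the split by control level (1185, highest other 1126). Its spleen had 1052 (1047), and burn spleen at 1 day 6692 (4863, split by control level). The 512, with injured replicate 2 and sham replicate 3 exchanged, and the 105 point to an untested structure of the arrays.

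Replicate 4 of the LPS shams at 2 hr lay at 0.78 of the way to the treated arrays over 422 genes, against -0.30 to 0.23 for the other shams. A treated mouse or its RNA under a sham label fits this. More granule-rich neutrophils without other LPS changes do not, since it lay at 0.82 over the 19 NF-kB genes (others -0.37 to 0.38), a test written before. A dimmer array does not either, with a control level of 1.103 times the median. A sham mouse with an infection of its own was not tested.

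The spleen 1 day after burn gave the most genes on 3 dim arrays. Dim arrays alone do not account for the falls: 2696 genes fell with the control level as a covariate, and the brighter replicate 4, a single array, showed the falls with a slope of 0.71 over 3178 genes. For the rises (2999, 1255 with that covariate) the slope of 0.25 over 2441 genes cannot exclude dim arrays. A fall of the same genes in blood, without dim arrays, fits: 1866 fell in both tissues, 2.76 times the number independent lists share. Rises shared numbered 496 (265 for independent lists), and 139 genes moved in opposite directions.

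Replicate 4 of the trauma-hemorrhage sham spleens at 7 day lay at 0.65 on the axis from burn sham to burn injury over 2209 genes, against 0.06 to 0.17 for the other shams of that time. Shams of other times were high too: replicate 4 at 2 hr (0.53, beyond the injured arrays of 2 hr at 0.13 to 0.26) and 3 day (0.45), and replicate 1 at 2 hr (0.33) and 3 day (0.28). A high position is thus not particular to 7 day, and whether an injured mouse or its RNA lies under the sham label stays open. An exchange with 1 of the injured arrays is argued against by their lowest position, 0.83, a test written before, and a dimmer array by a control level of 1.043 times the median. No biological explanation was tested.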

How the results depend on the processing

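The control level and Gapdh ratio covariates, leaving out dim arrays and scaling the LPS arrays were chosen after seeing the data. Where a count moved by over 1.5 times the cause was not tested. Counts moved in 17 of 29 results on the groups compared alone, 10 of 29 with the control level covariate, 3 of 29 with the Gapdh ratio, 8 of 11 without dim arrays, 4 of 29 after quantile normalization, 2 of 29 with a pseudocount of 1 and 1 of 29 with a pseudocount of 100, no filter or the mean of probe sets. Scaling the LPS arrays moved 1 of 5, and the hybridization day as a block 0 of 26. Named genes kept direction and side of the threshold in 751 of 799 results after quantile normalization, 749 with the control level, 772 with the Gapdh ratio, 690 on the groups compared alone and 240 of 284 without dim arrays. Leaving out replicates weakened 364 of 6216 and reversed 0. Gene list tests fell from 234 to 34 with an estimated correlation.

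On the groups compared alone, counts at 2 hr, 1 day, 3 day and 7 day were 449 and 1090 for burn blood (3 and 7 day), 134, 1483, 175 and 226 for trauma-hemorrhage blood, 55, 130 and 3654 for burn spleen (2 hr, 3 and 7 day), 1083, 47 and 342 for trauma-hemorrhage spleen (2 hr, 1 and 7 day) and 7 for LPS at 2 hr. Differences were 3663 (times, burn blood), 222 (times, trauma-hemorrhage blood), 960 (tissues, trauma-hemorrhage) and 4312 (LPS against burn). Quantile normalization gave 1171 and 737 for trauma-hemorrhage blood at 3 and 7 day, 9 for LPS times and 1331 for tissues after trauma-hemorrhage. The control level covariate gave 601 and 0 for trauma-hemorrhage blood at 3 and 7 day, 3951 for burn spleen at 1 day, 1547 and 1725 for trauma-hemorrhage spleen at 3 and 7 day, 135 for LPS at 2 hr, and 3808, 834 and 15 for times in burn spleen, trauma-hemorrhage blood and LPS, with 1330 for tissues after trauma-hemorrhage. The Gapdh ratio, which set injured apart from sham arrays in 4 of 18 comparisons (0.514 expected by chance; 0 of 18 for actin), gave 343 for trauma-hemorrhage blood at 7 day, 85 for LPS times and 1166 for LPS against trauma-hemorrhage, and of the 227 genes for LPS at 2 hr 112 were among the 216. Without dim arrays, trauma-hemorrhage blood at 3 day had 30, burn spleen 411, 2848 and 168 at 2 hr, 1 day and 3 day, times in burn spleen 2980, burn against trauma-hemorrhage in spleen 1655, tissues after burn 975 and LPS against trauma-hemorrhage 1482. The 30 and the 2848 come from 1 injured array each, assumed to vary like the other groups. Trauma-hemorrhage blood at 7 day and the differences that need it had no value there, since all 4 injured arrays were dim. A pseudocount of 1 gave 654 for trauma-hemorrhage blood at 7 day and 1 for LPS times, a pseudocount of 100 gave 43, no filter 13 and scaled LPS arrays 2 for LPS times, and the mean of probe sets 46 for burn spleen at 3 day.

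Directions turned for S100a9 in trauma-hemorrhage blood at 1 day (-0.00) and S100a8 and S100a9 at 7 day (-0.26 and -0.26) after quantile normalization, Alas2 there at 3 day without dim arrays (-0.28), Bpgm there at 7 day with the covariate (-0.00) and Cd74 in burn spleen at 1 day after quantile normalization (-0.30).

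Without each replicate in turn, counts ran for burn blood from 150 to 795 (2 hr), 52 to 187 (3 day) and 84 to 230 (7 day), for trauma-hemorrhage blood from 296 to 603, 1473 to 2443, 300 to 2729 and 272 to 2021, for burn spleen from 379 to 992 (2 hr) and 14 to 67 (3 day), for trauma-hemorrhage spleen from 348 to 493, 62 to 246 and 448 to 1188 (2 hr, 1 and 3 day), and for LPS from 77 to 422 and 0 to 2. Differences ran from 916 to 1257 (times, burn blood), 3784 to 6471 (burn spleen), 544 to 1833 (trauma-hemorrhage blood), 546 to 787 (its spleen), 0 to 154 (LPS), 1247 to 2230 and 1271 to 2345 (injuries in blood and spleen), 544 to 1581 and 1044 to 2032 (tissues after burn and trauma-hemorrhage), 1570 to 1843 (LPS against burn) and 74 to 537 (against trauma-hemorrhage).

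With the replicate block, LPS at 2 hr had 118 genes, LPS times 0 and LPS against trauma-hemorrhage 388, and 3 of 29 counts moved. In 0 of 18 comparisons were all 4 pairing correlations above 0.1, so the numbers do not pair the arrays.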

Other observations

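Sham animals also differed between times, which the comparisons with a sham of the same time leave out. In spleens of burn shams, 4 of 13 heat shock genes, whose products refold damaged proteins, were lower at 1 day than at 7 day (median -0.41). The HSP70 gene Hspa1b lay by -3.95 (SE 0.58, limma adjusted p = 5.9e-06), Hspa1a by -2.57 (SE 0.63) and the co-chaperone gene Dnajb1 by -1.28 (SE 0.31), genes chosen after their values were seen. Of 16 tissue macrophage genes 9 rose and 0 fell (median 1.31). Of 16 stroma and vessel genes, which mark other tissue, 4 rose and 0 fell (median 0.78), and 0 of 16 pancreas genes passed (median 0.75). With limma, 237 genes differed between these times, and 1610 between 2 hr and 7 day, where 2 of the 2 hr arrays were dim.

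In blood of trauma-hemorrhage shams, platelet genes were higher at 2 hr and 3 day than at 7 day, with 10 and 15 of 18 higher and 0 lower (medians 1.56 and 1.76), and 1 of 18 higher at 1 day (median 1.25). At 2 hr, where sham replicate 2 was dim (2.25 times the median control level), 3 of 23 B cell genes (median -0.87), 3 of 19 NK and cytotoxic cell genes (-1.04) and 4 of 18 monocyte genes (-0.35) were lower. Of 22 glucocorticoid-responsive genes 1 passed, Fkbp5, higher at 2 hr by 1.65 (SE 0.34, limma adjusted p = 0.00465). With limma, 290 genes differed at 2 hr, 12 at 1 day and 138 at 3 day. Burn sham blood had 1, 0 and 1 and trauma-hemorrhage sham spleen 0 at each time.

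A test chosen after seeing the result asked if blood 2 hr after trauma-hemorrhage is closer to LPS than after burn. From LPS sham (0) to treated (1) at 2 hr over 216 genes, trauma-hemorrhage lay at 1.01 ± 0.21 and burn at 0.24 ± 0.04. Over the 422 genes called without LPS sham replicate 4 they lay at 0.88 ± 0.16 and 0.22 ± 0.03 (n = 4 each). Effects of the same arrays had set the order (r with LPS 0.52 and 0.05), so the permutation p of 0.0286 cannot tell. The injuries differ in hybridization day, and LPS signals are smaller beside the pseudocount, so a 1 does not mean equal size.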
